A study of Homo sapiens with 10 samples.

How the data were processed

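RNA was measured by bulk sequencing in 10 libraries of TREx293 cells. These are human embryonic kidney cells that carry a tetracycline repressor and a recombination site, so that a construct placed at that site is expressed when doxycycline is added. The labels name 5 groups of 2 libraries: the control line (CTRL, genotype given as wild type) and lines carrying MN1, BEND2, the MN1-BEND2 fusion or the MN1-CXXC5 fusion. Per the labels' protocols the constructs carried an HA epitope tag, doxycycline induced expression, total RNA was extracted with Trizol, libraries were made with the VAHTS Universal V6 kit, and paired reads of 150 bases were sequenced on a DNBSEQ-T7 instrument. The labels do not say whether the control line received doxycycline. They also do not say whether the 2 libraries of a group came from separate cultures, so the p-values below measure the spread between these samples, which may be technical.

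The deposited table holds whole-number read counts per gene, with no normalization, and its columns were matched to the samples by name. No column of per-sample values was left unmatched (0 columns). Per the submitters' processing notes, HISAT2, SAMtools 1.0.1 and featureCounts 2.0.0 were used with the human genome build GRCh38 (hg38). Counting options, strand setting and annotation release are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and genes with near-identical copies or pseudogenes (histone, HOX and ribosomal protein genes, FTH1, RN7SL2) are uncertain. Reads of a construct and of the endogenous gene are likewise added together at MN1, BEND2 and CXXC5.

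The table had 58261 lines and 58216 gene identifiers. The 45 identifiers with 2 lines lie in the pseudoautosomal regions, and their lines were summed. Another 27 symbols had been turned into dates and were replaced by the GENCODE v29 name of the same identifier. All 58216 identifiers were found in GENCODE v29, which supplied positions on GRCh38, and 57353 symbols equalled the name given there. Total counts per library were 15.9 to 26.8 M (M for 1e6). A floor of 3 counts corresponds to between 0.112 and 0.189 counts per 1e6 counts (CPM), depending on the library. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

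Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM scaling, filterByExpr by group), with Benjamini-Hochberg adjustment over 18127 tested genes and calls at an adjusted p under 0.05. All 10 libraries entered one fit with group as the only factor, which left 5 residual degrees of freedom. The common biological coefficient of variation was 0.04. Levels are CPM with TMM factors and are printed as mean ± SD over the 2 libraries of a group, and SE is the standard error of a log2 fold change. A gene absent from one group is given a lower bound against a floor of 3 counts over the group. A gene with 1 to 3 counts in one group is given the ratio of depth-scaled counts with an exact 95% binomial interval. The 8 comparisons set each construct against control, the MN1-BEND2 fusion against MN1 and against BEND2, the MN1-CXXC5 fusion against MN1, and one fusion against the other. Genes called in the same direction in several comparisons were counted in 3 intersections.

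Before the data were examined, 38 gene lists with 885 members were fixed for pathways, cell types and complexes. Of the members, 883 were matched, 859 by the symbol in the table and 24 through the current symbol of the gene identifier. Each list with at least 5 tested members was tested with camera (limma 3.58.1, inter-gene correlation preset at 0.01, two-sided, adjusted over the lists within a comparison). This covered 37 lists, and the hepatocyte markers had too few tested members. Counts of members were also adjusted over the list alone. Camera made 59 calls in the 8 comparisons. With an estimated correlation, 14 of the 59 held, and all 59 were called by fry, which asks only whether a list moves one way on balance. Lists that keep their call with an estimated correlation are named as such below.

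The named genes followed a rule that was also set before the data were examined, as were the groups, the comparisons and the tests. MN1, BEND2 and CXXC5 come first. For each comparison against control, the rule takes the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the groups. Genes without a proper symbol, with clone-based or non-coding style names and pseudogenes were left out. Comparisons between constructs contribute the 5 largest rises and 5 largest falls, and intersections the 10 highest and 5 lowest by their smallest change. For each called list, up to 4 members with the smallest adjusted p were taken. Genes chosen after their values were seen are described as such. A few results that the rule selects are not reported here.

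The test was tried on simulated data for the comparison of MN1-BEND2 with control, with counts drawn for the 18127 genes and 4 sets of 50 changed genes. It recovered 20% of genes changed 1.2-fold, 48% changed 1.5-fold, 62% changed 2-fold and 88% changed 4-fold. Of 17907 unchanged genes, 15 were called. These were 15 of 131 calls in all, a larger share of false calls than the threshold on adjusted p aims at. In the same simulation, camera called a list with added changes and did not call an unchanged list. With a simulated GC trend the test made 3393 calls, and 16 once offsets for GC content and length were included.

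Alternatives planned before the data were examined were median-of-ratios size factors, library totals alone, no low-count filter, a replicate block, only the compared groups in the fit, DESeq2 1.42.0, leaving out each library in turn, and camera with an estimated correlation or fry. With 1 library left in a group, that library was assumed to vary like the other groups. Alternatives added after seeing the data were leaving out both libraries with salivary transcripts and smooth offsets for GC content and transcript length in each library. Shared controls were examined with 20 simulations in which all 10 libraries, the 2 controls included, were drawn with no change between groups. These simulations cover random spread only and hold no shift of the deposited control libraries. The controls could not be split, since each part would hold 1 library.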

Results

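The libraries held 19.0 and 23.4 M counts in control cells, 18.1 and 19.1 M in MN1 cells, 26.8 and 15.9 M in BEND2 cells, 18.6 and 24.5 M in MN1-BEND2 cells, and 17.1 and 18.0 M in MN1-CXXC5 cells. Replicate libraries correlated at 0.9908 to 0.9933 across genes, which are not independent replicates, and differed by more than counting noise in each group (chi-square per degree of freedom 2.12 to 3.52). The first principal component, 32.7% of the variance, set the MN1-BEND2 libraries (57.4 and 55.8) apart from the other 8 (-24.0 to -5.4). The second, 24.5% of the variance, set the MN1-CXXC5 libraries apart (-44.3 and -44.6). Transcripts typical of salivary gland and squamous epithelium were most abundant in CTRL replicate 1 and MN1 replicate 1. The 18 genes first seen, such as KRT4, KRT13, ZG16B and MUC7, summed to 129 and 117 CPM there and to between 2.82 and 5.48 CPM in the other 8 libraries. Fold changes also followed GC content by group. In MN1-BEND2 cells the median log2 fold change against control was -0.23 in the 20% of genes with the lowest GC content and 0.26 in the 20% with the highest, and in MN1-CXXC5 cells it was 0.06 and -0.40, while replicates of one group differed by at most 0.02 in either set.

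The genes placed in the constructs were read first. MN1 encodes a transcriptional co-regulator, BEND2 a protein with BEN domains and CXXC5 a zinc-finger protein that binds CpG DNA. MN1 (chromosome 22, 27748277 to 27801498) stood at 3.91 and 3.81 CPM in the control libraries, 328 and 325 in MN1 cells, 291 and 291 in MN1-BEND2 cells, 128 and 128 in MN1-CXXC5 cells, and 5.39 and 4.93 in BEND2 cells. BEND2 (chromosome X, 18162931 to 18220883) stood at 390 and 399 CPM in BEND2 cells and 394 and 407 in MN1-BEND2 cells. It had 0 and 4 counts in control, 0 and 6 in MN1 cells, and 7 and 10 in MN1-CXXC5 cells. CXXC5 (chromosome 5, 139647299 to 139683882) stood at 13.6 and 13.4 CPM in control, 8.36 and 9.10 in MN1 cells, 12.9 and 12.4 in BEND2 cells, 22.9 and 21.9 in MN1-BEND2 cells, and 55.2 and 61.9 in MN1-CXXC5 cells. The levels went with the labels in all 10 libraries. Against control, MN1 was higher by a log2 fold change of 6.40 in MN1 cells, 6.24 in MN1-BEND2 cells and 5.05 in MN1-CXXC5 cells (SE 0.049, 0.049 and 0.052; adjusted p = 2.08e-15, 2.93e-15 and 7.35e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its level was lower in MN1-CXXC5 than in MN1 cells by -1.35 (SE 0.031, edgeR adjusted p = 7.13e-11), so MN1 reads were not at equal levels. Counts per gene also depend on how much of the gene a construct carries. The levels of the constructs themselves are therefore not known from them. BEND2 did not differ detectably between MN1-BEND2 and BEND2 cells (0.02, SE 0.06, edgeR adjusted p = 0.807). CXXC5 rose in MN1-CXXC5 cells (2.12, SE 0.07, edgeR adjusted p = 1.44e-09) and by less in MN1-BEND2 cells (0.73, SE 0.075, edgeR adjusted p = 5.84e-06), and it fell in MN1 cells (-0.63, SE 0.089, edgeR adjusted p = 0.000135). In BEND2 cells MN1 was called higher (0.44, SE 0.09, edgeR adjusted p = 0.0271), but the call ended in 7 of 12 alternatives, such as without BEND2 replicate 1 (0.36, adjusted p = 0.288; range over the alternatives 0.0177 to 0.288). BEND2 was called higher in MN1-CXXC5 cells from 17 counts against 4 (2.32, SE 0.838, edgeR adjusted p = 0.0409), and that call ended in 6 of 12 alternatives (adjusted p 0.00406 to 0.165).

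**Figure D1:**
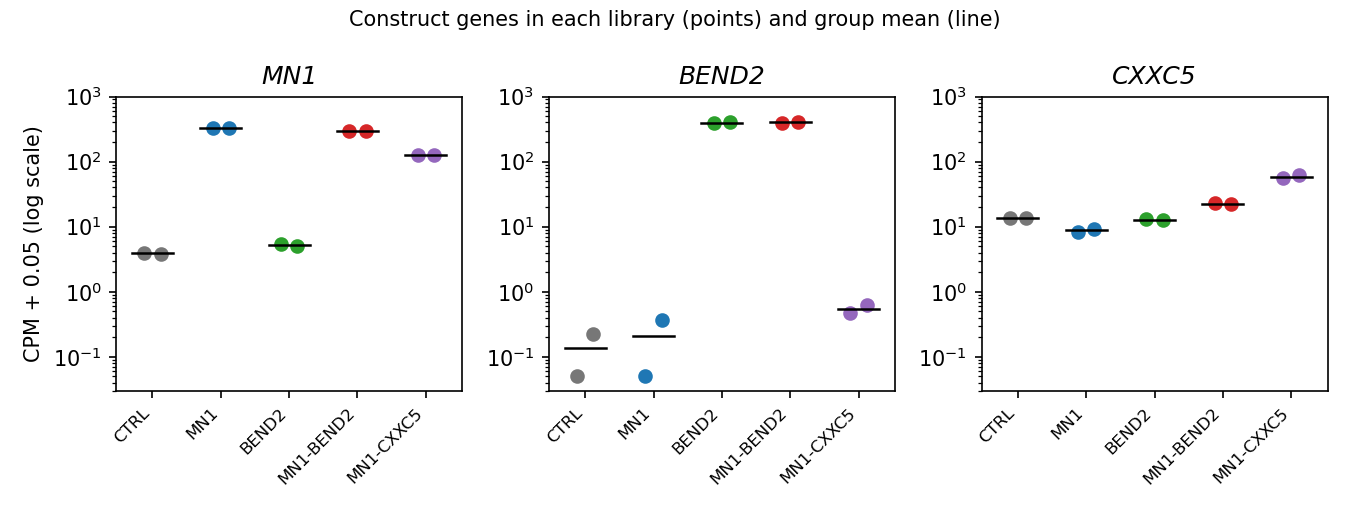
Levels of MN1, BEND2 and CXXC5 in CPM plus 0.05 on a log axis, with a point for each of the 10 libraries and a line for the mean of each group. MN1 is high in the 3 groups with an MN1 part, BEND2 near 400 CPM in the BEND2 and MN1-BEND2 groups, and CXXC5 highest in the MN1-CXXC5 group.

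The first comparison set MN1-BEND2 cells against control. After BEND2 itself, the largest rises were in KCNQ3, a potassium channel subunit, GABRA2, a GABA receptor subunit, DOK6, a docking adaptor of receptor kinases, and FLRT2, a cell adhesion protein of guided axons. These genes were almost silent in control: KCNQ3 had 230 counts in the 2 fusion libraries and 1 in control (ratio 225, 95% interval 40.0 to 8925), GABRA2 401 and 2 (196, 53.9 to 1625), DOK6 223 and 1 (218, 38.8 to 8654), and FLRT2 382 and 2 (187, 51.4 to 1548). ADRA2A, an adrenergic receptor gene (chromosome 10, 111077163 to 111080907), rose from 0.584 ± 0.384 to 96.8 ± 4.53 CPM (SD, n = 2; log2 fold change 7.30, SE 0.173, edgeR adjusted p = 3.74e-11). The protocadherin gene PCDH10 (chromosome 4, 133149315 to 133208606) rose from 0.479 ± 0.133 to a mean of 25.2 CPM (5.73, SE 0.233, edgeR adjusted p = 2.43e-09). Rises of 5.91 and 5.66 were seen for ADCYAP1, the gene of the neuropeptide PACAP, and SV2C, a synaptic vesicle protein (edgeR adjusted p = 3.31e-08 and 3.21e-08). Falls were smaller. DDR2, a collagen-binding receptor kinase (chromosome 1, 162631373 to 162787400), fell from 55.3 ± 3.36 to 8.05 ± 1.10 CPM (-2.80, SE 0.077, edgeR adjusted p = 1.3e-10). CHEK2, a DNA damage checkpoint kinase (chromosome 22, 28687743 to 28742422), fell from 52.2 ± 0.11 to 11.1 ± 0.278 CPM (-2.22, SE 0.047, edgeR adjusted p = 1.91e-11). The other large falls were C5orf63 (-2.77), the inhibin subunit gene INHBE (-2.59), the meiotic recombination gene MND1 (-2.28), the receptor gene TNFRSF9 (-2.24), the teneurin gene TENM1 (-2.10), the collagen hydroxylase gene P3H2 (-2.05), the secreted glycoprotein gene STC1 (-2.00) and C11orf71 (-1.99).

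Of 16 MAPK feedback targets, genes switched on by the MAP kinase pathway, 10 rose, 2 fell and 4 were not called (median log2 fold change 0.71, camera adjusted p = 5.78e-05, adjusted p = 0.061 with an estimated correlation). The transcription factor gene ETV5 rose by 1.28, the cyclin gene CCND1 by 1.08 and the phosphatase gene DUSP4 by 1.14. Of 16 immediate early genes, transcription factors induced within minutes of a stimulus, 10 rose and 2 fell, or 10 and 3 adjusted over the list alone (median 0.53, camera adjusted p = 5.78e-05, adjusted p = 0.061 with an estimated correlation). MYC rose from 105 ± 1.68 to 326 ± 1.65 CPM (1.64, SE 0.03, edgeR adjusted p = 5.09e-12), JUNB by 2.26 and NR4A3 by 2.63. Replication-dependent histone genes rose in 9 of 13 and fell in 0, with the same counts adjusted over the list alone (median 0.89, camera adjusted p = 6.98e-06, adjusted p = 0.061 with an estimated correlation). Linker histone HIST1H1C rose by 1.85 and HIST1H2BK by 1.38. Targets of ATF4, a transcription factor of the integrated stress response, went the other way: 19 of 22 fell and 1 rose, also adjusted over the list alone (median -0.65, camera adjusted p = 1.72e-09), and the call held with an estimated correlation (adjusted p = 0.029). The cystine transporter gene SLC7A11 fell from 184 ± 3.74 to 62.4 ± 1.28 CPM (-1.56, SE 0.035, edgeR adjusted p = 2.58e-11), the serine synthesis gene PSAT1 by -0.82 and TRIB3 by -0.94. Cholesterol synthesis genes rose in 15 and fell in 1 of 22, or 16 and 1 adjusted over the list alone (median 0.32, camera adjusted p = 0.000238, adjusted p = 0.061 with an estimated correlation). HMGCS1 stood at 0.75 and SQLE at 0.80. Heat shock genes rose in 8 of 10, or 9 up and 1 down adjusted over the list alone (median 0.33, camera adjusted p = 0.00934, adjusted p = 0.66 with an estimated correlation), such as the co-chaperone gene BAG3 (0.95).

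In all, 9416 of 18127 genes were called, 4841 higher and 4575 lower, of which 863 rose and 421 fell by at least 1 on the log2 scale. With offsets for GC content and length, 73.2% of these calls stayed in the same direction, the balance turned to 3918 higher and 4480 lower, and the medians of immediate early and cholesterol genes moved to 0.29 and 0.18.

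MN1-CXXC5 cells against control gave the second fusion. SV2C led the rises, from 0.126 ± 0.117 to 5.39 ± 0.0021 CPM (log2 fold change 5.44, SE 0.325, edgeR adjusted p = 1.6e-07), followed, after MN1, by SLC24A2, a sodium-calcium exchanger gene (4.99, from 0.548 ± 0.109 to 17.5 ± 0.682 CPM), and PCDH10 (3.55). COL12A1, a collagen chain gene (chromosome 6, 75084326 to 75206051), rose from 13.04 ± 1.28 to 90.7 ± 2.45 CPM (2.79, SE 0.059, edgeR adjusted p = 5.51e-11). Rises of 2.66, 2.50, 2.49, 2.41 and 2.27 were seen for the sarcomere gene MYOM2, the WNT modulator DKK2, the nuclear receptor NR4A3, the neurotrophin gene BDNF and the developmental transcription factor PAX2. The top fall in the ranking, BAG6 (-4.29, edgeR adjusted p = 0.00949), rested on CTRL replicate 2: without that library it was -1.02 (adjusted p = 0.413), without MN1-CXXC5 replicate 2 it was -3.57 (0.0757), and over the 12 alternatives adjusted p ranged from 3.4e-68 to 0.413. Firm falls were the lipase inhibitor G0S2 (-3.17), INHBE (-2.59), the laminin chain LAMB3 (-2.51), the ferritin receptor gene SCARA5 (-2.49), the mTOR inhibitor DDIT4 (-2.34), ID3, an inhibitor of basic helix-loop-helix factors (-2.31), the guidance factor SEMA3C (-2.13), C5orf63 (-2.07) and HOXD8 (-1.95). DDIT4 went from 96.7 ± 4.30 to 19.1 ± 3.03 CPM (SE 0.077, edgeR adjusted p = 1.35e-09) and ID3 from 25.6 ± 1.90 to 5.16 ± 0.487 CPM (SE 0.107, edgeR adjusted p = 2.24e-08).

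ATF4 targets fell in 20 of 22 and rose in 0, with the same counts adjusted over the list alone (median -0.79, camera adjusted p = 6.22e-27), and this held with an estimated correlation (adjusted p = 0.00242). Besides DDIT4, the mitochondrial enzyme gene PCK2 fell by -1.19 and SLC7A11 by -1.01. HOX genes, which pattern the body axis, rose in 19 and fell in 4 of 36 (median 0.27, camera adjusted p = 9.41e-06, adjusted p = 0.0291 with an estimated correlation, the same counts adjusted over the list alone). HOXA13 rose from 85.4 ± 0.0888 to 204 ± 0.182 CPM (SE of the log2 fold change 0.034, edgeR adjusted p = 3.77e-10) and HOXC6 by 1.02. Cholesterol synthesis genes rose in 12 and fell in 6 of 22, also adjusted over the list alone (median 0.20, camera adjusted p = 1.34e-10, adjusted p = 0.012 with an estimated correlation). IDI1 stood at 1.83, INSIG1 at 1.08 and MSMO1 at 0.98. Cytosolic ribosomal protein genes fell in 33 and rose in 8 of 59, also adjusted over the list alone (median -0.14, camera adjusted p = 1.17e-08, adjusted p = 0.0412 with an estimated correlation), led by RPL13 (-0.96) and RPLP0 (-0.66). The remaining calls were lost with an estimated correlation. MAPK feedback targets rose in 8 and fell in 2 of 16, or 9 and 2 adjusted over the list alone (median 0.31, camera adjusted p = 0.0132, adjusted p = 0.221 with an estimated correlation). CCND1 stood at 1.02 and SPRY1, a feedback inhibitor, at -0.75. Glycolysis and hypoxia genes fell in 14 and rose in 2 of 21, or 16 and 2 adjusted over the list alone (median -0.45, camera adjusted p = 4.96e-05, adjusted p = 0.287 with an estimated correlation). ENO1 fell by -0.55 and PGK1 by -0.51, while the glucose transporter gene SLC2A3 rose by 1.08. Heat shock genes rose in 8 and fell in 1 of 10, also adjusted over the list alone (median 0.28, camera adjusted p = 0.000629, adjusted p = 0.467 with an estimated correlation), such as HSPE1 (0.83). Mitochondrially encoded genes rose in 11 of 13 and fell in 0, or 12 and 0 adjusted over the list alone (median 0.52, camera adjusted p = 0.000767, adjusted p = 0.573 with an estimated correlation). MT-ND2 stood at 0.67 and MT-ATP6 at 0.69. Epithelial junction and keratin genes fell in 5 and rose in 0 of 17, also adjusted over the list alone (median -0.69, camera adjusted p = 0.0137, adjusted p = 0.287 with an estimated correlation). KRT19 stood at -1.48 and KRT8 at -0.69.

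The comparison called 8033 genes, 3489 higher and 4544 lower, of which 287 rose and 652 fell by at least 1. The excess of falls depended on the processing, with 2926 higher and 5135 lower under library totals and 3606 and 3477 with GC and length offsets, and DESeq2 called 4984. GC and length explained 16.8% of the variance of the fold changes. With offsets for them 72.2% of calls stayed in the same direction, the medians of ATF4 targets and epithelial genes moved to -0.52 and -0.29, and the call of KRT18 ended (-0.39 with edgeR adjusted p = 0.000488, then -0.17 with 0.0638; range over the alternatives 1.4e-11 to 0.0638).

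MN1 cells against control gave the unfused MN1 protein. The largest rise after MN1 was NTS, the gene of the neuropeptide neurotensin (chromosome 12, 85874295 to 85882992), from 3.91 ± 0.143 to 48.7 ± 1.15 CPM (log2 fold change 3.64, SE 0.107, edgeR adjusted p = 7.69e-10). IGSF10 (3.25), C1QTNF3 (2.61), the G protein regulator RGS4 (2.47), the transcription factor RFX6 (2.14) and CCDC80 (1.98) also rose. LY6E (2.99) and SYNRG (2.09) were in the same ranking, but their calls ended without CTRL replicate 2, with similar folds (2.65 and 1.92, adjusted p = 0.0674 and 0.0722). That of SYNRG also ended without MN1 replicate 1 (1.86, 0.0615). The lowest adjusted p over the alternatives was 7.02e-38 for LY6E and 2.43e-21 for SYNRG, and the highest for SYNRG was 0.105. Among falls, the nutrient-sensing arrestin genes TXNIP and ARRDC4 went from 112 ± 0.0153 to 20.8 ± 0.59 CPM (-2.43, SE 0.041, edgeR adjusted p = 5.36e-12) and from 329 ± 4.62 to 65.1 ± 1.70 CPM (-2.34, SE 0.034, edgeR adjusted p = 1.6e-12). TSC22D3, a glucocorticoid-induced leucine zipper gene, fell from 1105 ± 21.4 to 321 ± 2.37 CPM (-1.78, SE 0.029, edgeR adjusted p = 4.2e-12). G0S2 (-2.77), BFAR (-2.40), INHBE (-2.26), GDAP1L1 (-2.25) and SCARA5 (-1.88) fell as well. FRG1 (-3.22) and SINHCAF (-1.87) each rested on a single control library: FRG1 was -0.28 without CTRL replicate 2 (adjusted p = 0.867, range over the alternatives 8.2e-56 to 0.867) and SINHCAF -0.52 without CTRL replicate 1 (adjusted p = 0.434, range 2.28e-79 to 0.559). Both calls also ended without either MN1 library (FRG1 -2.95 and -3.57 with 0.132 and 0.0973, SINHCAF -1.86 and -1.88 with 0.0998 and 0.101).

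Cholesterol synthesis genes rose in 20 of 22 and fell in 0, also adjusted over the list alone (median 0.61, camera adjusted p = 1.36e-20, adjusted p = 0.00241 with an estimated correlation). MSMO1 rose by 1.06 and SQLE by 0.81. ATF4 targets fell in 20 and rose in 1 of 22, also adjusted over the list alone (median -0.75, camera adjusted p = 4.03e-22, adjusted p = 0.00241 with an estimated correlation), such as the stanniocalcin gene STC2 (-0.85) and ATF3 (-1.36). Targets of the tumour suppressor p53 fell in 18 and rose in 2 of 25, also adjusted over the list alone (median -0.32, camera adjusted p = 5.81e-06, adjusted p = 0.0335 with an estimated correlation). GDF15 stood at -3.14, EDA2R at -1.15 and MDM2 at -0.46. GDF15 and SESN2 are also on the list of ATF4 targets, so the calls of these lists are not fully separate. Immediate early genes fell in 10 and rose in 1 of 16, or 11 and 1 adjusted over the list alone (median -0.35, camera adjusted p = 5.25e-05, adjusted p = 0.0462 with an estimated correlation). KLF6 stood at -1.17 and JUN at -0.61. The calls from here on were lost with an estimated correlation. MAPK feedback targets fell in 10 and rose in 2 of 16, also adjusted over the list alone (median -0.51, camera adjusted p = 0.00584, adjusted p = 0.128 with an estimated correlation). DUSP4 stood at -1.45, ETV5 at -1.02 and CCND1 at 0.63. Notch targets fell in 4 and rose in 1 of 10, also adjusted over the list alone (median -0.35, camera adjusted p = 0.0071, adjusted p = 0.193 with an estimated correlation). HES1 stood at -1.01 and HEY1 at -1.07. Histone genes fell in 9 and rose in 0 of 13, also adjusted over the list alone (median -0.68, camera adjusted p = 0.00625, adjusted p = 0.137 with an estimated correlation), such as HIST1H2AC (-1.56). Glycolysis and hypoxia genes fell in 11 and rose in 1 of 21, or 12 and 2 adjusted over the list alone (median -0.14, camera adjusted p = 6.4e-08, adjusted p = 0.131 with an estimated correlation). NDRG1 stood at -1.42, VEGFA at -1.14 and PGAM1 at 0.75. Heat shock genes rose in 8 of 10, also adjusted over the list alone (median 0.36, camera adjusted p = 1.11e-09, adjusted p = 0.131 with an estimated correlation). DNAJB1 stood at 0.79 and HSPE1 at 0.64. Endoplasmic reticulum chaperone genes rose in 9 and fell in 4 of 16, or 9 and 5 adjusted over the list alone (median 0.19, camera adjusted p = 0.0108, adjusted p = 0.138 with an estimated correlation). HSPA5 stood at 0.89 and SDF2L1 at 1.30. Ribosomal protein genes rose in 31 and fell in 7 of 59, or 33 and 7 adjusted over the list alone (median 0.11, camera adjusted p = 0.00728, adjusted p = 0.184 with an estimated correlation). RPLP2 stood at 0.58. HOX genes rose in 11 and fell in 2 of 36, or 10 and 2 adjusted over the list alone (median 0.14, camera adjusted p = 0.0473, adjusted p = 0.138 with an estimated correlation). HOXA13 stood at 0.62 and HOXA11 at 0.79. The HOX call also ended without CTRL replicate 1 (camera adjusted p = 0.0599), without MN1 replicate 2 (0.0796) and in 3 other alternatives (range 8.69e-05 to 0.138).

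The comparison called 7786 genes, 3909 higher and 3877 lower, of which 281 rose and 296 fell by at least 1. Both groups include a library with salivary transcripts, and without these libraries 5373 genes were called. DESeq2 called 4862, and library totals turned the balance to 3509 higher and 4221 lower.

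BEND2 cells against control changed least. Calls at the top of the ranking depended on single libraries: FAN1 (log2 fold change 2.13), CLK2 (1.91), ACACA (1.58) and PUF60 (1.08) rose with edgeR adjusted p = 0.0242, 0.0278, 0.017 and 0.0476. The calls of FAN1, CLK2, ACACA and PUF60 ended on leaving out CTRL replicate 2 (1.98, 1.11 and 0.99 for the first 3, with adjusted p = 0.137, 0.0821, 0.103 and, for PUF60, 0.134). All but FAN1 also ended without BEND2 replicate 1 (CLK2 1.58 with 0.192, ACACA 1.17 with 0.17 and PUF60 0.36 with 0.573), FAN1 and CLK2 without BEND2 replicate 2 (1.59 and 2.15 with 0.157 and 0.0627), and FAN1 and PUF60 without CTRL replicate 1 (2.26 and 0.99 with 0.0891 and 0.18). The folds mostly stayed large, and that of PUF60 did not shrink without CTRL replicate 2. Over the alternatives the lowest adjusted p of FAN1, CLK2, ACACA and PUF60 was 7e-24, 3.6e-38, 1.5e-28 and 1e-25. Steadier rises were those of RFX6 (1.02, SE 0.181, edgeR adjusted p = 0.00392), the actin-severing gene SCIN (0.85, from 15.3 ± 0.435 to 27.7 ± 0.78 CPM, SE 0.053, edgeR adjusted p = 5.73e-06), SDF2L1 (0.83), NTS (0.81) and LRRC3 (0.81). BAG6 led the falls (-3.49, edgeR adjusted p = 0.0392) but stood at -0.22 without CTRL replicate 2 (adjusted p = 0.913, range over the alternatives 8.1e-58 to 0.913), and its call ended without either BEND2 library (-3.79 and -3.32, adjusted p = 0.186 and 0.176). BFAR fell by -2.27, DDR2 from 55.3 ± 3.36 to 18.5 ± 0.624 CPM (-1.58, SE 0.067, edgeR adjusted p = 3.7e-07), GDAP1L1 by -1.35, CLVS2 by -1.23, INHBE by -0.83, the stress-induced gene NUPR1 by -0.79 and ZC3H6 by -0.76. G0S2 (-0.78) and TCEAL7 (-0.76) were called as well, but not without CTRL replicate 2 (-0.70 and -0.57, adjusted p = 0.103 and 0.119) or either BEND2 library (-0.67 and -0.89 for G0S2, adjusted p = 0.152 and 0.0558; -0.74 and -0.78 for TCEAL7, 0.0972 and 0.0637), with ranges over the alternatives of 0.000842 to 0.152 and 0.001 to 0.119.

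Cholesterol synthesis genes rose in 15 of 22 and fell in 0, or 16 and 0 adjusted over the list alone (median 0.40, camera adjusted p = 2.22e-29, adjusted p = 0.00196 with an estimated correlation). INSIG1 rose from 137 ± 2.05 to 205 ± 3.44 CPM (0.58, SE 0.034, edgeR adjusted p = 3.28e-06), SQLE by 0.57 and HMGCS1 by 0.50. ATF4 targets fell in 11 of 22 and rose in 0, or 15 and 1 adjusted over the list alone (median -0.18, camera adjusted p = 3.42e-13, adjusted p = 0.00712 with an estimated correlation). ALDH1L2, an enzyme of mitochondrial folate metabolism, stood at -0.61 and SLC7A11 at -0.42. G2/M genes fell in 7 and rose in 1 of 26, or 15 and 2 adjusted over the list alone (median -0.10, camera adjusted p = 0.0063, adjusted p = 0.658 with an estimated correlation). HMMR, a spindle gene, fell by -0.38 and AURKB, a mitotic kinase, rose by 0.20, a call that ended with DESeq2 (0.19, adjusted p = 0.0694, range over the alternatives 0.000301 to 0.0694). With GC and length offsets the list's camera adjusted p was 0.238 (median -0.05, range over the alternatives 0.000237 to 0.658). Heat shock genes rose in 3 of 10, or 6 adjusted over the list alone (median 0.16, camera adjusted p = 0.0035, adjusted p = 0.658 with an estimated correlation). Without CTRL replicate 1 their camera adjusted p was 0.0505, and HSPE1 (0.34) and HSPH1 (0.23) were no longer called (0.25 and 0.17, edgeR adjusted p = 0.0756 and 0.101; ranges over the alternatives 2.41e-06 to 0.0756 and 1.04e-06 to 0.107).

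In all 2569 genes were called, 1217 higher and 1352 lower, of which 32 rose and 25 fell by at least 1. The balance turned to 1328 higher and 1138 lower under library totals and to 1567 and 1335 with no low-count filter. The count was 1077 without BEND2 replicate 1, 1214 without BEND2 replicate 2, 1264 without CTRL replicate 2, 1372 without CTRL replicate 1, 1285 without both libraries with salivary transcripts, 1655 with GC and length offsets and 861 with DESeq2.

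**Figure D2:**
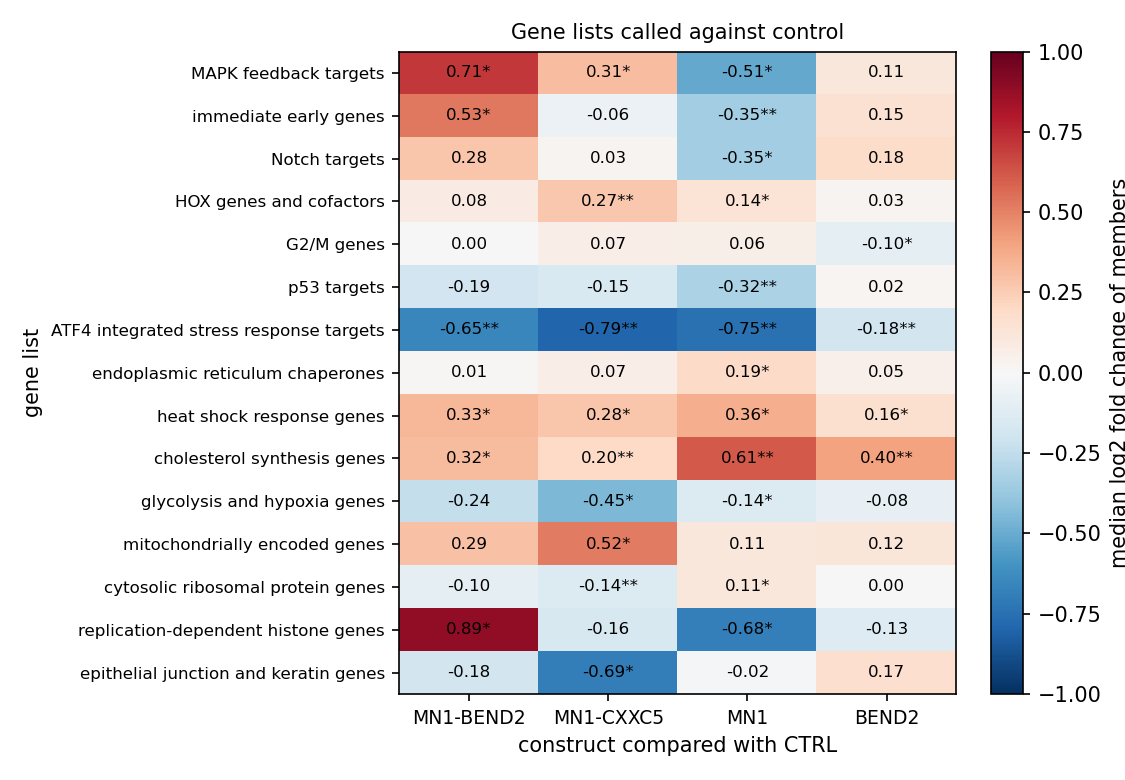
Median log2 fold change against control of the 15 gene lists called in at least 1 of the 4 comparisons, as a heat map with lists as the vertical and constructs as the horizontal axis. A star marks a camera adjusted p under 0.05 with the preset correlation and a double star one that also holds with an estimated correlation: ATF4 targets are lower in all 4 columns, at -0.65, -0.79, -0.75 and -0.18.

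MN1-BEND2 cells against MN1 cells compare the fusion with unfused MN1, each in its own line. KCNQ3 had 230 counts against 0 (at least 64.5-fold higher, over the group), GABRA2 401 against 2 (ratio 169, 95% interval 46.4 to 1398) and FLRT2 382 against 2 (161, 44.2 to 1332), while ADRA2A rose by a log2 fold change of 6.61 (SE 0.165, edgeR adjusted p = 7.21e-11). The top of the falls, the keratin genes KRT4 (1 count against 317, ratio 377, 95% interval 67.1 to 14930, edgeR adjusted p = 0.0452) and KRT13 (-4.80, 0.0265), belongs to the salivary transcripts of MN1 replicate 1. Without that library the KRT4 call ended (2 counts left in MN1 cells, adjusted p = 0.854, range over the alternatives 7.2e-87 to 0.854) and KRT13 -2.37 (0.366, range 1e-76 to 0.366), and both calls also ended without either MN1-BEND2 library (KRT4 0.137 and 0.183; KRT13 0.0853 and 0.138, at similar folds of -5.39 and -4.29). NTS fell from 48.7 ± 1.15 to 4.01 ± 0.59 CPM (-3.59, SE 0.106, edgeR adjusted p = 2.68e-10), the secreted factor gene OSTN by -3.52 and the heparan sulfate enzyme gene NDST4 by -2.88. Immediate early genes were higher in 13 of 16 and lower in 0, also adjusted over the list alone (median 1.28, camera adjusted p = 2.95e-15, adjusted p = 0.00678 with an estimated correlation). MYC stood at 1.83, JUNB at 2.51 and ATF3 at 1.27. MAPK feedback targets were higher in 13 and lower in 2 of 16, also adjusted over the list alone (median 1.07, camera adjusted p = 4.03e-12, adjusted p = 0.00678 with an estimated correlation). DUSP4 stood at 2.60, ETV5 at 2.30 and ETV4 at 1.78. Histone genes were higher in 11 of 13 and lower in 0, also adjusted over the list alone (median 1.73, camera adjusted p = 1.01e-13, adjusted p = 0.00678 with an estimated correlation). HIST1H1C stood at 2.10 and HIST1H2AC at 2.56.

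The other calls of this comparison were lost with an estimated correlation. TGF-beta and BMP targets rose in 10 of 14, or 10 up and 1 down adjusted over the list alone (median 0.42, camera adjusted p = 0.000496, adjusted p = 0.269 with an estimated correlation). ID1 stood at 2.14 and ID2 at 1.44. Notch targets rose in 6 of 10, also adjusted over the list alone (median 0.51, camera adjusted p = 0.00255, adjusted p = 0.269 with an estimated correlation). HEY2 stood at 2.19 and JAG1, a Notch ligand, at 0.78. Extracellular matrix and mesenchymal genes rose in 13 and fell in 7 of 28, also adjusted over the list alone (median 0.17, camera adjusted p = 0.00765, adjusted p = 0.124 with an estimated correlation). The collagen cross-linking enzyme genes LOX and LOXL2 rose by 2.61 and 2.85, while the collagen gene COL5A1 fell by -1.21. With no low-count filter this list's camera adjusted p was 0.0713, and with GC and length offsets its median was 0.10 (range of adjusted p over the alternatives 7.79e-06 to 0.124). Ribosomal protein genes fell in 39 and rose in 2 of 59, or 40 and 2 adjusted over the list alone (median -0.15, camera adjusted p = 0.000207, adjusted p = 0.124 with an estimated correlation), such as RPS15 (-0.44). G1/S and replication genes fell in 20 and rose in 5 of 28, or 21 and 5 adjusted over the list alone (median -0.23, camera adjusted p = 0.00765, adjusted p = 0.133 with an estimated correlation). MCM6 stood at -0.35, UHRF1 at -0.64 and RRM2 at 0.90. Cholesterol synthesis genes fell in 13 and rose in 2 of 22, also adjusted over the list alone (median -0.21, camera adjusted p = 0.00872, adjusted p = 0.124 with an estimated correlation). MSMO1 stood at -0.84. HOX genes fell in 17 and rose in 9 of 36, also adjusted over the list alone (median -0.18, camera adjusted p = 0.0414, adjusted p = 0.148 with an estimated correlation), such as HOXA5 (-0.85). The HOX call also ended without MN1 replicate 2 (camera adjusted p = 0.0629), without MN1-BEND2 replicate 1 (0.0503) and in 2 other alternatives (range 3.38e-05 to 0.148), and its median was -0.28 with GC and length offsets. In all, 8398 genes were called, 4201 higher and 4197 lower, of which 913 rose and 396 fell by at least 1. DESeq2 called 5343, and the balance was 3701 higher and 4660 lower with GC and length offsets and 4660 and 3676 under library totals.

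Against BEND2 cells, which carry unfused BEND2 in their own line, the MN1-BEND2 fusion had higher ADRA2A (log2 fold change 7.55, SE 0.178, edgeR adjusted p = 6.18e-11). FLRT2 had 382 counts against 3 (ratio 127, 95% interval 43.0 to 617) and KCNQ3 230 against 3 (76.3, 25.8 to 373). GABRA2 rose by 6.53 and ADCYAP1 by 5.92 (edgeR adjusted p = 5.42e-08 and 5.07e-08). CLK2 (-2.94, edgeR adjusted p = 0.00108), a gene whose replicates differed 5.23-fold in control, led the falls. It was followed by C5orf63 (-2.46), TENM1 (-2.45), the chemokine gene CXCL8 (-2.30) and CHEK2 (-2.14, SE 0.048, edgeR adjusted p = 4.2e-11). Histone genes rose in 11 of 13, also adjusted over the list alone (median 1.28, camera adjusted p = 1.65e-09, adjusted p = 0.0674 with an estimated correlation). HIST1H2BJ stood at 1.72. Immediate early genes rose in 9 and fell in 1 of 16, also adjusted over the list alone (median 0.38, camera adjusted p = 1.22e-05, adjusted p = 0.0674 with an estimated correlation). JUNB stood at 2.06 and MYC at 1.41. MAPK feedback targets rose in 10 and fell in 2 of 16, also adjusted over the list alone (median 0.57, camera adjusted p = 7.11e-05, adjusted p = 0.0943 with an estimated correlation). ETV5 stood at 1.34 and DUSP4 at 1.26. ATF4 targets fell in 16 of 22 and rose in 0, or 17 and 0 adjusted over the list alone (median -0.33, camera adjusted p = 7.11e-05, adjusted p = 0.0674 with an estimated correlation). SLC7A11 stood at -1.14. The comparison called 7909 genes, 3933 higher and 3976 lower, of which 721 rose and 306 fell by at least 1, and DESeq2 called 4832.

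The MN1-CXXC5 fusion was set against MN1 cells in the same way. SV2C (log2 fold change 5.55), SLC24A2 (5.30), COL12A1 (3.79, from 6.54 ± 0.586 to 90.7 ± 2.45 CPM, SE 0.07, edgeR adjusted p = 2.62e-11), TMEM132B (3.72) and the progesterone receptor gene PGR (3.67) rose most. NTS led the falls (-4.68, SE 0.125, edgeR adjusted p = 2.07e-10). KRT13 (-4.66, edgeR adjusted p = 0.0336) again came from MN1 replicate 1, and without it stood at -2.20 (adjusted p = 0.406, range over the alternatives 3.7e-67 to 0.406). Its call also ended without either MN1-CXXC5 library, with similar folds (-4.32 and -5.10, adjusted p = 0.137 and 0.12). The interferon receptor gene IFNGR2 fell by -3.39, with replicates far apart in MN1 cells (22.1 ± 17.7 CPM), the enamel matrix gene AMBN by -3.32 and SEMA3C by -2.99 (from 78.9 ± 2.59 to 9.90 ± 0.141 CPM, SE 0.074, edgeR adjusted p = 1.18e-10). Every list call here was lost with an estimated correlation. Ribosomal protein genes fell in 42 and rose in 4 of 59, or 45 and 6 adjusted over the list alone (median -0.30, camera adjusted p = 4.04e-13, adjusted p = 0.059 with an estimated correlation), such as RPLP2 (-0.78) and RPS19 (-0.88). MAPK feedback targets rose in 10 and fell in 2 of 16, also adjusted over the list alone (median 0.49, camera adjusted p = 8.91e-06, adjusted p = 0.059 with an estimated correlation). DUSP4 stood at 2.48, ETV5 at 1.84 and DUSP6 at 1.44. Immediate early genes rose in 9 and fell in 1 of 16, also adjusted over the list alone (median 0.71, camera adjusted p = 0.000453, adjusted p = 0.0845 with an estimated correlation). NR4A2 stood at 1.85.

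The remaining 6 list calls of this comparison ended without MN1 replicate 1 and in 1 or 2 other alternatives each, for example with no low-count filter for stem cell and neuronal genes (camera adjusted p = 0.241 and 0.119). Hedgehog targets rose in 6 and fell in 1 of 10, or 8 and 1 adjusted over the list alone (median 0.88, camera adjusted p = 0.0347, adjusted p = 0.222 with an estimated correlation). The receptor gene PTCH1 stood at 0.88 and NKX2-2 at 1.51. Notch targets rose in 4 and fell in 1 of 10, or 4 and 2 adjusted over the list alone (median 0.27, camera adjusted p = 0.0308, adjusted p = 0.243 with an estimated correlation). HEY1 stood at 1.73 and HES4 at -1.46. Neural stem cell and radial glia markers rose in 6 and fell in 4 of 18, or 7 and 4 adjusted over the list alone (median 0.15, camera adjusted p = 0.0359, adjusted p = 0.222 with an estimated correlation). TNC stood at 2.55 and the transporter gene SLC1A3 at -0.50. Neuronal differentiation genes rose in 6 and fell in 3 of 14, also adjusted over the list alone (median 0.20, camera adjusted p = 0.0458, adjusted p = 0.222 with an estimated correlation). The neurofilament gene NEFL stood at 1.68 and SNAP25 at 1.29. Histone genes rose in 7 and fell in 1 of 13, also adjusted over the list alone (median 0.56, camera adjusted p = 0.0347, adjusted p = 0.222 with an estimated correlation), such as HIST1H2AC (1.38). Epithelial genes fell in 8 and rose in 0 of 17, also adjusted over the list alone (median -0.66, camera adjusted p = 0.0347, adjusted p = 0.222 with an estimated correlation). KRT19 stood at -1.52. Without MN1 replicate 1, camera adjusted p was 0.0593 for 5 of these lists and 0.0661 for the neuronal genes (ranges over the alternatives reached from 7.75e-08 to 0.243), and with GC and length offsets the medians of stem cell, neuronal and Notch genes were 0.07, 0.47 and 0.83. The comparison called 8842 genes, 4216 higher and 4626 lower, of which 342 rose and 951 fell by at least 1. The balance turned to 4722 higher and 4336 lower with no low-count filter and to 3845 and 3759 without the salivary libraries, and 65.8% of calls stayed in the same direction with GC and length offsets.

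The fusions were also compared directly. MN1-BEND2 cells had more GABRA2 (401 against 2 counts, ratio 158, 95% interval 43.5 to 1310), ADRA2A (log2 fold change 6.60, SE 0.168, edgeR adjusted p = 1.19e-10), DOK6 (4.81) and ADCYAP1 (4.64) than MN1-CXXC5 cells. They had less TMEM132B (-2.63), CHEK2 (-2.20, SE 0.049, edgeR adjusted p = 5.06e-11), SLC24A2 (-2.07), DDR2 (-2.02) and MND1 (-2.00). Histone genes were higher in 11 of 13, also adjusted over the list alone (median 0.94, camera adjusted p = 0.000189, adjusted p = 0.112 with an estimated correlation). HIST1H2BJ stood at 1.87. HOX genes were lower in 22 and higher in 3 of 36, also adjusted over the list alone (median -0.36, camera adjusted p = 0.00159, adjusted p = 0.112 with an estimated correlation). HOXA13 stood at -0.95. Immediate early genes were higher in 10 and lower in 3 of 16, or 11 and 3 adjusted over the list alone (median 0.59, camera adjusted p = 0.00193, adjusted p = 0.121 with an estimated correlation). JUNB stood at 2.52 and EGR1 at 1.80. Epithelial genes were higher in 9 and lower in 1 of 17, also adjusted over the list alone (median 0.38, camera adjusted p = 0.0157, adjusted p = 0.426 with an estimated correlation). KRT8 rose from 111 ± 8.54 to 375 ± 2.10 CPM (1.76, SE 0.044, edgeR adjusted p = 1.19e-10) and the mucin gene MUC1 by 2.34. Ribosomal protein genes were higher in 31 and lower in 15 of 59, or 32 and 16 adjusted over the list alone (median 0.11, camera adjusted p = 0.0484, adjusted p = 0.498 with an estimated correlation). RPL13 stood at 1.12. Their median turned to -0.02 with GC and length offsets (camera adjusted p = 0.705), and their call also ended without MN1-BEND2 replicate 1 (0.059), without MN1-CXXC5 replicate 1 (0.0615), with median-of-ratios scaling (0.0964) and without the salivary libraries (0.134; range over the alternatives 2.71e-05 to 0.705). This comparison had the steepest GC trend of the 8, with medians of -0.28 and 0.66 in the 20% of genes with the lowest and highest GC content. With offsets, camera adjusted p was 0.0876 for immediate early genes (median 0.15) and 0.053 for epithelial genes, the HOX median was -0.56, and 58.8% of calls stayed in the same direction. The calls numbered 10624, with 5645 higher and 4979 lower, of which 1526 rose and 376 fell by at least 1. The balance turned to 3900 higher and 4430 lower with the offsets, and library totals gave 6074 and 4331.

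Changes that both fusions share against control were counted next. Leaving out MN1, which both constructs carry, SV2C, PCDH10 and COL12A1 led the genes that rose in both fusions against control. COL12A1 rose by 3.47 (SE 0.056) in MN1-BEND2 and 2.79 (SE 0.059) in MN1-CXXC5 cells (edgeR adjusted p = 2.44e-12 and 5.51e-11). MYOM2 rose by 2.68 and 2.66, though its MN1-BEND2 replicates lay far apart (35.6 ± 18.2 CPM), DKK2 by 2.82 and 2.50, NR4A3 by 2.63 and 2.49, BDNF by 2.25 and 2.41, the matrix glycoprotein gene EMILIN2 by 3.10 and 2.23, and SHISA2 by 2.94 and 1.87. INHBE fell by -2.59 in each, C5orf63 by -2.77 and -2.07, G0S2 by -1.91 and -3.17, SCARA5 by -1.87 and -2.49, and the methyltransferase gene N6AMT1 by -1.73 and -1.82. In all, 1531 genes rose and 1644 fell in both, against 932 and 1147 for independent lists, and 2078 moved in opposite directions against 2094. DESeq2 called 1734 in both, with the balance turned to 944 higher and 790 lower. Unchanged groups simulated together with the 2 controls they share had 0.65 calls in common on average and at most 2 in 20 runs. The fold changes correlated at 0.39 across genes, against 0.48 simulated, with a covariance of 0.151 against 0.035 simulated. MN1-BEND2 and MN1 cells shared 2206 rises and 2346 falls (1044 and 979 for independent lists). Their fold changes correlated at 0.34, against 0.48 simulated, with a covariance of 0.12 against 0.035 simulated. Part of each excess may come from the shared controls, and the simulations, which hold no shift of the controls, cannot say how much.

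**Figure D3:**
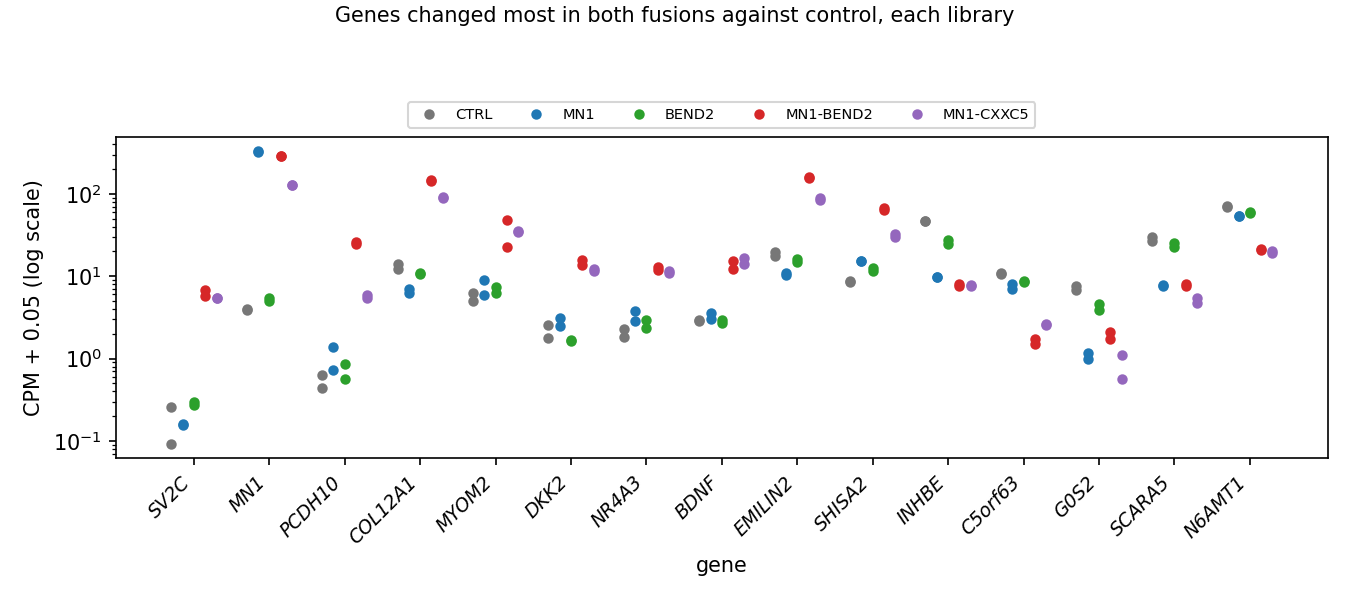
CPM plus 0.05 on a log axis for the 15 genes that lead the changes common to both fusions, with a point for each library by group. SV2C lies at 6.23 and 5.39 CPM on average in the fusion groups and at 0.126 CPM in control, and INHBE at 7.75 and 7.72 against 46.6 CPM.

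Genes on which MN1-BEND2 cells differed in the same direction from control, MN1 and BEND2 cells numbered 4734, with 2434 higher and 2300 lower, and DESeq2 called 2961. FLRT2, ADRA2A, GABRA2, KCNQ3, ADCYAP1, DOK6, SV2C, PCDH10, BMP2 and KCNK13 led the rises. The morphogen gene BMP2 (chromosome 20, 6767664 to 6780280) stood at 35.3 ± 0.00409 CPM against 0.863 ± 0.253 in control, 0.629 ± 0.0565 in MN1 and 1.45 ± 0.38 in BEND2 cells (log2 fold changes 5.37, 5.80 and 4.54, edgeR adjusted p = 3.41e-10, 3.71e-10 and 7.49e-10). The potassium channel gene KCNK13 rose by 4.31, 3.97 and 4.07. C5orf63, CHEK2, MND1, ZNF233 and C11orf71 led the falls, CHEK2 by -2.22, -2.02 and -2.14. MN1-CXXC5 cells differed in the same direction from control and MN1 cells in 4792 genes, with 2010 higher and 2782 lower. The excess of falls depended on the processing, with 1670 higher and 3042 lower under library totals and 1723 each with the offsets, and DESeq2 called 2965. SV2C, SLC24A2, COL12A1, PCDH10, PAX2, EMILIN2, MYOM2, BDNF, CXXC5 and TMEM132B led the rises, with PAX2 at 2.27 and 2.93. SEMA3C, ID3, FTH1, RN7SL2 and BAD led the falls. The ferritin gene FTH1, which has many pseudogenes, stood at -1.91 and -2.29, RN7SL2, a signal recognition particle RNA with near-identical copies, at -1.77 and -1.95, and the apoptosis gene BAD at -1.68 and -1.84.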

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

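Of the tests in this part, those on the 18 salivary genes first seen, on ATF4 targets and on small changes were chosen after the results were seen, as were the genes named as examples of opposite changes. The first results to look at again are genes called in opposite directions against control in different construct groups, which therefore differ between these groups. Their counts lie below those for independent lists, which are 2022, 668, 1726 and 2094 in the order given here. MN1-BEND2 and MN1 cells had 1014 such genes, 512 higher with the fusion and lower with MN1, 502 the other way, and 35 changed over 2-fold in both. The transcription factor gene ONECUT3 stood at a log2 fold change of 2.98 with the fusion and -3.54 with MN1. The progesterone receptor gene PGR stood at 2.38 and -1.96, the neurotrophin receptor gene NGFR at 2.84 and -1.54, and NOV at 3.39 and -1.25. The lists that moved this way were MAPK feedback targets, immediate early genes and histone genes, higher with the fusion and lower with MN1 (direct comparison, camera adjusted p = 4.03e-12, 2.95e-15 and 1.01e-13). The direct calls held with an estimated correlation (adjusted p = 0.00678 each), but those against control were lost for the fusion (0.061 each) and, in MN1 cells, for MAPK feedback targets and histone genes (0.128 and 0.137).

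MN1-BEND2 and BEND2 cells had 154 such genes, 98 of them higher with the fusion, with PGR at 2.38 and -1.15 and SLITRK5 at 1.72 and -1.12. MN1-CXXC5 and MN1 cells had 1586, of which 1060 were lower with the fusion. NTS stood at -1.04 with the fusion and 3.64 with MN1, AMBN at -1.36 and 1.96, and TMEM132B at 2.10 and -1.62. MAPK feedback targets were higher with this fusion and lower with MN1 (direct comparison, camera adjusted p = 8.91e-06), and ribosomal protein genes the reverse (4.04e-13). Both direct calls were lost with an estimated correlation (adjusted p = 0.059 each), as were those of MAPK feedback targets against control (0.221 and 0.128) and of ribosomal protein genes in MN1 cells (0.184). The fusions moved in opposite directions in 2078 genes, 1320 of them higher in MN1-BEND2 cells. MTFP1 stood at 1.85 and -1.51, F12 at 1.51 and -1.41, and FTH1 at 1.17 and -1.91. Against control, genes with the highest GC content had median changes of 0.26 in MN1-BEND2, -0.4 in MN1-CXXC5 and 0.13 in MN1 cells. With offsets for GC content and length, 58.8% of calls between the fusions stayed in the same direction and 553 turned. For MN1-CXXC5 against MN1 cells these values were 65.8% and 186. Genes called alike in both fusions numbered 3652 with the offsets, against 3175. How many of the 2078 and 1586 genes depend on GC content was not tested.

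Salivary and squamous transcripts were seen in CTRL replicate 1 and MN1 replicate 1, with ZG16B at 502 and 422 counts there and 2 and 0 in the other libraries of these groups. ZG16B also had 23, 13 and 3 counts in replicate 1 of MN1-BEND2, MN1-CXXC5 and BEND2 cells and 0 in their replicate 2. The leukocyte gene PTPRC had 24 and 19 counts in MN1-BEND2 and MN1-CXXC5 replicate 1 and at most 2 in the other libraries, and IL2RB 24 and 7 against at most 5. RNA from oral or salivary tissue remains a candidate source. Among 34 genes not looked at before with at least 5 counts, 44.1% had these libraries as their 2 highest, short of the 50% set for this source and above the 10% set against it. The summed level of these genes in replicate 1 over replicate 2 was 1.85 in control and 2.16 in MN1 cells. In the other 8 libraries their level was already 50.5% of that in these 2, which hides a small added share. The ratio therefore cannot decide, and expression by the cells themselves stays open too. Among salivary genes, MUC7 had 340 and 238 counts in these 2 libraries, CRISP3 58 and 50, and PIP 52 and 50. Each had 0 in replicate 2 of control and of MN1 cells. In contrast, PRB1, AMY1A and HTN3 had 0 in every library and STATH at most 5. Counting options are not given, so a 0 is uncertain for a gene with near-identical copies. The genes first seen differed 28.5-fold in control and 25.3-fold in MN1 cells. They were picked after their values were seen, so these ratios describe the genes and are no test of a source.

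ATF4 targets were lower than in control under every construct. In MN1-BEND2 cells 16 of 22 members were lower than in BEND2 cells and none was higher, though camera's adjusted p was 0.0674 with an estimated correlation. That comparison holds no control library. A shift of the control libraries alone would leave these groups alike, so it was excluded as the whole cause in both at once. For either group alone it stays open as the whole cause, since the other may have moved by itself. In BEND2 cells the median was -0.18, with 11 of 22 lower than control. MN1 and MN1-CXXC5 cells were not set against BEND2 cells. The other comparisons without control did not call the list. Between MN1-BEND2 and MN1 cells 10 members rose and 5 fell (median 0.17, camera adjusted p = 0.542). For MN1-CXXC5 against MN1 cells the counts were 5 and 12 (-0.23, 0.37), and for MN1-BEND2 against MN1-CXXC5 cells 13 and 6 (0.43, 0.356). A control shift common to these groups therefore stays open. The salivary transcripts in CTRL replicate 1 were excluded as well, since without both libraries that carry them all 4 comparisons against control called the list lower (camera adjusted p = 1.7e-10, 1.52e-28, 2.27e-22 and 5.99e-14). An effect of the expressed constructs is a hypothesis that these tests leave standing. By the same 16 members, doxycycline missing from control alone is excluded as the whole cause in MN1-BEND2 and BEND2 cells at once. For either group alone it stays open, in part or as the whole, since the labels do not say whether control cells received it. Handling that differed between the cultures was not tested. Cholesterol synthesis and heat shock genes were called higher than control under every construct. Between MN1-BEND2 and BEND2 cells neither list was called (medians -0.02 and 0.16, camera adjusted p = 0.929 and 0.112). Cholesterol genes were lower in MN1-BEND2 than in MN1 cells in 13 and higher in 2 of 22. A shift of the control libraries was not tested for these 2 lists and stays open.

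Most called genes changed by small amounts, with a median absolute log2 fold change among calls of 0.42, 0.39, 0.36 and 0.23 in MN1-BEND2, MN1-CXXC5, MN1 and BEND2 cells. A smooth trend of each library with GC content and transcript length was not the whole cause in the first 3 comparisons. There at least 72.2% of calls stayed in the same direction with offsets for it. The offsets remove only such a smooth trend, so other differences tied to GC content or length stay open. For BEND2 cells 54.3% stayed, and this cause cannot be told apart from others. The bounds, under 50% for the cause and at least 67% against it, were set for the 4 comparisons together, which gave no decision, and were applied to the parts after the result was seen. Scaling was not excluded: at least 90.4% stayed under median-of-ratios factors and library totals, but these moved the median of all genes by at most 0.046 and so could not decide. Whether GC content differed through RNA handling, library preparation or the constructs remains open, because replicates of a group may have been processed together, and GC content and length together explained 33.5% of the variance of the fold changes between the fusions.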

How the results depend on the processing

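Of the alternatives in this part, leaving out both salivary libraries and the GC and length offsets were tests chosen after the data were seen. Of 414 named results, 29 had a call or a direction that changed under some alternative. Median-of-ratios factors changed none of the 414, and library totals, no filter and the replicate block changed 1 each, all to a call gained. Fitting only the compared groups ended 2 calls, the GC and length offsets 8 and leaving out both salivary libraries 9. DESeq2 ended 5 and left 392 unchanged, and the other named results had no adjusted p there and were not compared. It gave no adjusted p for 9840 of the 18127 tested genes in BEND2 against control, the most of the 8 comparisons. Over all runs without a single library, 59 calls of named genes ended, 1 was gained and 3 directions turned. Of the 59 list calls, 59 held with fry, 58 with median-of-ratios factors, 57 with library totals, 56 with no filter, 55 with the replicate block, 54 with the offsets, 52 without both salivary libraries and 14 with an estimated correlation. Over the runs without a single library, 223 list calls held and 13 ended.

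Counts of genes stayed within 1.5 times in 48 of 52 runs without a single library, and the others were those of BEND2 against control: 1077 without BEND2 replicate 1, 1214 without BEND2 replicate 2, 1264 without CTRL replicate 2 and 1372 without CTRL replicate 1, against 2569. That comparison called 1285 genes without both salivary libraries, 1655 with the offsets, 861 with DESeq2 and 4159 with the replicate block. Replicate differences correlated between groups by 0.07 to 0.29, all positive and 9 of 10 over 0.1, and replicate 2 had the higher share of counts from the mitochondrial chromosome in all 5 groups. Libraries with the same number thus share a weak difference, and whether the numbers mark pairs remains open. Fewer libraries explain part of the first counts by construction, and for the others the cause was not tested.

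DESeq2 called fewer genes in each comparison. It gave 4984 for MN1-CXXC5 and 4862 for MN1 against control, 5343 for MN1-BEND2 against MN1 and 4832 against BEND2. In the intersections it gave 1734 for both fusions, 2961 for MN1-BEND2 and 2965 for MN1-CXXC5, and the cause was not tested. Its counts for the other comparisons were within 1.5 times: 6427 for MN1-BEND2 against control, 6141 for MN1-CXXC5 against MN1 and 7789 between the fusions. The balance of rises and falls also moved. For both fusions DESeq2 gave 944 higher and 790 lower, and for MN1 against control no filter gave 3495 and 4311. Against control, library totals gave 3509 higher and 4221 lower for MN1 and 1328 and 1138 for BEND2, where the report has more rises for MN1 and more falls for BEND2. For MN1-BEND2 against MN1 the offsets gave 3701 higher and 4660 lower, and library totals 4660 and 3676. For the MN1-BEND2 intersection the offsets gave 2069 higher and 2185 lower. For the MN1-CXXC5 intersection they gave 1723 each. The offsets turned the direction of 553 calls between the fusions, 186 of MN1-CXXC5 against MN1, 111 of MN1-CXXC5 and 49 of MN1-BEND2 against control.

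Among the named genes, the sign turned for BEND2 alone. In MN1 cells against control, with 6 and 4 counts, the fitted value was 4.74 without CTRL replicate 2, -0.06 without CTRL replicate 1 and -4.01 without MN1 replicate 2, and no alternative called it (edgeR adjusted p 0.141 to 0.970). Between MN1-BEND2 and BEND2 cells it was 0 to 0.05 on leaving out single libraries, against 0.02. So few counts explain the first, and for the second the cause was not tested. Depth limits genes under 0.112 to 0.189 CPM, the level of 3 counts.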

Other observations

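The tests of families, of the neighbours of CHEK2 and of differences between replicates were chosen after the results were seen, and the genes named in this part after their values were seen. The list of growth factors and receptor tyrosine kinases was not called in MN1-BEND2 cells against control (18 of 36 rose and 10 fell, median log2 fold change 0.23, camera adjusted p = 0.501). Of its members, PDGFRA rose from 1.75 ± 0.555 to 11.2 ± 0.251 CPM (2.65, SE 0.2, edgeR adjusted p = 4.15e-07), FGFR1 from 70.0 ± 1.05 to 149 ± 2.31 CPM (1.09, SE 0.042, edgeR adjusted p = 1.66e-09), and FGFR3 and NTRK2 rose by 1.24 and 1.32. FGFR1 was slightly lower in MN1-CXXC5 and MN1 cells (-0.23 and -0.17, edgeR adjusted p = 0.00152 and 0.00945). The ligand gene PDGFA rose in MN1-CXXC5 cells and fell in MN1 cells (1.16 and -0.99, edgeR adjusted p = 4.4e-06 and 5.71e-05), with no call in MN1-BEND2 cells. Axon guidance genes went both ways, 14 of 36 up and 15 down in MN1-BEND2 cells (median -0.17, camera adjusted p = 0.188), with ROBO3 at 2.51 and PLXNA2 at -1.44 (edgeR adjusted p = 4.26e-10 and 7.12e-09). Brain patterning transcription factors rose in 13 and fell in 3 of 26 (median 0.35, camera adjusted p = 0.319), with DLX5 at 1.28.

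The matrix enzyme gene LOX rose from 45.8 ± 0.0885 to 327 ± 2.96 CPM in MN1-BEND2 cells (2.83, SE 0.034, edgeR adjusted p = 1.7e-13) and to 87.2 ± 2.13 CPM in MN1-CXXC5 cells (0.93, SE 0.036, edgeR adjusted p = 5.99e-09). N-cadherin, CDH2, fell from 136 ± 4.24 to 62.0 ± 3.13 CPM in MN1-BEND2 cells (-1.14, SE 0.053, edgeR adjusted p = 7.19e-09). The astrocyte intermediate filament gene GFAP was low in control (1.39 ± 0.339 CPM), was not called in MN1-BEND2 cells (-0.19, edgeR adjusted p = 0.578) and fell in MN1-CXXC5 cells (-1.06, edgeR adjusted p = 0.0158). Astrocyte markers rose in 6 and fell in 5 of 17 in MN1-BEND2 cells, where the median (-0.17) and the direction of the test (up) differed in sign (camera adjusted p = 0.688). CLU, one of the proteins astrocytes secrete, fell by -0.97 in MN1-BEND2 and -1.12 in MN1-CXXC5 cells.

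The other lists with no call in any of the 8 comparisons were as follows in MN1-BEND2 cells against control. Oligodendrocyte precursor markers rose in 4 and fell in 3 of 11, with a median of 0.23 and a test pointing down (camera adjusted p = 0.718). Ependymal and motile cilia genes rose in 6 and fell in 3 of 20, WNT targets in 5 and 2 of 13, and retinoid response genes in 5 and 3 of 10 (camera adjusted p = 0.958, 0.718 and 0.519). BAF complex subunits rose in 12 and fell in 7 of 29, Polycomb subunits in 6 and 11 of 25, and interferon-stimulated genes in 8 and 3 of 21 (each camera adjusted p = 0.519). NF-kappaB and cytokine genes rose in 3 and fell in 4 of 14, kidney and nephron progenitor markers in 6 and 2 of 14, and meiosis and germline genes in 3 and 1 of 11 (camera adjusted p = 0.572, 0.519 and 0.519). Blood cell markers rose in 2 of 7 and fibroblast markers in 2 of 5 (camera adjusted p = 0.718 and 0.688).

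Families formed from symbol prefixes with at least 12 tested members were examined after the data were seen. In MN1 cells against control, 279 of 508 ZNF genes fell and 26 rose (median -0.28, camera adjusted p = 7.44e-10, adjusted p = 0.119 with an estimated correlation). Subunits of respiratory complex I named NDUFB rose in 9 of 12 (median 0.48, camera adjusted p = 8.67e-05, adjusted p = 0.157 with an estimated correlation). Between MN1-BEND2 and MN1 cells, 24 of 32 HIST genes rose and 0 fell (median 1.31, camera adjusted p = 1.56e-15, adjusted p = 0.0298 with an estimated correlation), and no other family call held with an estimated correlation.

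Of 11696 genes with at least 5 CPM, 26 differed over 4-fold between the replicates of a group, up to 237-fold for ZG16B, one of the salivary transcripts, and 47.7-fold for NDUFA6. They include 2 genes in the pseudoautosomal regions and 2 in the major histocompatibility complex. Near CHEK2, which fell in MN1-BEND2 cells, the neighbours HSCB, CCDC117, KREMEN1 and ZNRF3 were not called (0.20, -0.03, -0.14 and 0.06, edgeR adjusted p = 0.123, 0.446, 0.0866 and 0.497) and XBP1 fell by -0.46 (edgeR adjusted p = 2.03e-07).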
